A study of Arabidopsis thaliana with 4 samples.

How the data were processed

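Non-strand-specific mRNA sequencing libraries were made from 5 µg of total RNA of Arabidopsis root tips with the TruSeq RNA Sample Prep kit, per the labels' protocols. Seedlings of Col-0 and med16-2 were grown on agar medium with 1 mM or 5 µM phosphate and were sampled 4 days after germination. Each of the 4 groups (Col-0 high phosphate, Col-0 low phosphate, med16-2 high phosphate, med16-2 low phosphate) has 1 library, and groups were taken from the genotype and treatment labels. The authors deposited 1 file of counts per library, whole numbers of reads per locus with no normalization, covering 33602 loci. Per the submitters' processing notes, Trimmomatic 0.35, TopHat2 2.0.9 and HTSeq 0.6.0 were used with TAIR10; their settings, and the annotation release, are not given in the sources used here. Counts came from libraries that do not keep strand, so reads of overlapping and antisense loci cannot be told apart, and the files list reads that align to several places apart from the gene counts, which can lower the counts of near-identical genes.

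The files also hold lines that name no gene, which were kept out of library sizes and comparisons. They took 12.5%, 9.89%, 10.1% and 42.1% of all reads listed for Col-0 high phosphate, Col-0 low phosphate, med16-2 high phosphate and med16-2 low phosphate. In the same order, 9.27%, 6.65%, 7.18% and 36.6% were reads aligned to several places, 1.41%, 1.31%, 1.21% and 4.43% fell in no annotated gene, and 1.84%, 1.93%, 1.76% and 1.12% were ambiguous. The remaining gene counts of 10079345, 15696333, 14266585 and 12302510 set the depth, at which a count of 0 allows up to 0.305, 0.188, 0.208 and 0.245 CPM (3 counts). Gene names and biotypes, and which loci overlap, were taken from the TAIR10.1 annotation for 32835 loci matched by locus identifier; its coordinates served for overlaps alone.

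Libraries were scaled with edgeR's trimmed mean of M values (TMM), with factors of 0.9774, 1.017, 1.0091 and 0.997. Of all loci, 9306 had no count in any library, and the 18692 with a mean TMM-scaled CPM of at least 1 over the 4 libraries were compared. Log2 ratios were taken on counts plus 0.5 over the effective library size. The 95% interval of a ratio was exact (Clopper-Pearson on the share of both libraries' counts). A gene met the size rule with a ratio of at least 2-fold and an interval excluding equality. For the difference of phosphate log2 ratios the interval was normal, with a variance of the sum of 1/(count + 0.5), and had to exclude 0. With 1 library per group these rules compare libraries, not conditions, and no p-value was attached to them. A ratio against a library at 0 counts was given as a bound against 3 counts in that library.

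The 19 gene lists (282 genes, 234 passing the filter), the comparisons, the rule for named genes and the alternatives other than the 1 named as added were set before the data were examined. The lists were systemic phosphate starvation, the local phosphate and aluminium pathway of STOP1 and ALMT1, iron uptake, iron storage, root stem cell niche, cell cycle, root hair, root cap, xylem, phloem, differentiated endodermis, lateral root initiation, photosynthetic shoot tissue, Mediator subunits, defence, cold, auxin, heat shock and touch, and reference genes. The median of each list with at least 5 measured members was placed among the medians of 10000 random lists of the same size, drawn with replacement from 10 bins of expression. Named genes were a fixed set of genes (MED16, STOP1, ALMT1, LPR1, IPS1, AT4, SPX1, SPX3, PHT1;4, PAP17, PLT1, WOX5, CYCB1;1, FIT, IRT1 and FER1), the 6 genes with the largest ratio in each direction among those meeting the size rule with a mean CPM of at least 5, and up to 4 members of each list with the largest absolute ratio. PAP10, PAP12, PAP24, PHF1, CASP1, SQD1, SQD2, MGD2, MGD3, NPC4, GDPD1, PLDZ2, RSL4, RHS18, COR47, ERD10, RNS1 and JAZ10 were also named in comparisons where that rule did not take them, and were chosen after their values had been seen.

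The size rule was tested on simulated counts with 200 genes altered by known folds, drawn at the depth of each library. These were Poisson draws around a shared mean per gene, without variation between plants. The false calls and interval coverage below therefore hold for counting error alone, not for differences between real plants. Genes altered 1.5-fold were called in 2.0% of cases for phosphate in Col-0, 2.0% for phosphate in med16-2, 4.0% for genotype at high phosphate, 2.0% for genotype at low phosphate and 4.0% for the difference of phosphate ratios. In the same order, genes altered 2.5-fold were called in 91.7%, 98.0%, 94.0%, 96.0% and 88.0% of cases, those altered 4-fold in 100%, 95.9%, 100%, 100% and 100%, and those altered 8-fold in 100%, 100%, 100%, 100% and 98.0%. Unaltered genes called numbered 39, 41, 39, 36 and 113, and intervals held the true ratio for 95.7%, 95.4%, 95.4%, 95.6% and 94.9% of genes. In a simulation of the additive model for phosphate, edgeR recovered 194 of 194 genes with 6 false calls and DESeq2 173 of 194 with 1 false call. Those genes were altered 4-fold alike in both genotypes, with no genotype effect, no interaction and the same dispersion for all genes. The simulation therefore does not show how the models fare where the phosphate ratio depends on the genotype.

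Alternatives were DESeq2 size factors, total counts and upper-quartile factors for scaling, no filter or a mean CPM of at least 5, thresholds of 1.5-fold and 4-fold, an interval beyond 2-fold, a pseudocount of 5, random lists without matching, lists without their member of largest ratio, and additive models of genotype and phosphate in edgeR (quasi-likelihood) and DESeq2 (Wald test). The additive models have 1 residual degree of freedom, which is the interaction of genotype and phosphate. Leaving out ribosomal RNA, mitochondrial and plastid loci was added after the data had been seen; it was first run with libraries rescaled, and was changed, once counts had been seen, to leave out those 61 loci with the scaling kept. The software was R 4.3.3, edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0, Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.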

Results

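RNA was sequenced from root tips of Arabidopsis thaliana seedlings collected 4 days after germination. Col-0, the reference accession, and med16-2, a mutant line of the gene for Mediator subunit 16, were each grown with 1 mM phosphate (high phosphate) or with 5 µM phosphate (low phosphate). Mediator is the protein complex that links DNA-bound transcription factors to RNA polymerase II. The labels give 1 library per group, 4 libraries in all, so no difference between libraries has a replicate check and no p-value was computed for any 2-library comparison. The total count over genes was 10079345 in Col-0 at high phosphate, 15696333 in Col-0 at low phosphate, 14266585 in med16-2 at high phosphate and 12302510 in med16-2 at low phosphate. A gene is called higher or lower below only if it met a size rule: a difference of at least 2-fold and an exact 95% interval of the ratio that excluded equality, among the 18692 loci with a mean of at least 1 CPM (count scaled to library size). Values in parentheses after a fold or a log2 ratio are these 95% intervals, which cover counting error only and not the variation between plants. Gene list medians are medians of log2 ratios, and their position among 10000 random lists matched on expression describes these 4 libraries.

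The library of med16-2 at low phosphate differed from the other 3 in its make-up. Reads aligned to several places made up 36.6% of its reads, against 9.27% in Col-0 at high phosphate, 6.65% in Col-0 at low phosphate and 7.18% in med16-2 at high phosphate. The 18S ribosomal RNA locus AT3G41768 took 1.37% of its gene counts, against 0.17% in Col-0 at high phosphate and 0.10% in both of the remaining libraries. Mitochondrial loci took 0.50%, 1.25%, 0.23% and 1.03% of gene counts in Col-0 at high and low phosphate and in med16-2 at high and low phosphate. These shares are repeated beside the groups of loci that moved with them.

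MED16 (AT4G04920), the gene disrupted in med16-2, was measured in every library as a check of the labels. It had 420 counts in Col-0 at high phosphate, 747 in Col-0 at low phosphate, 56 in med16-2 at high phosphate and 48 in med16-2 at low phosphate. Between genotypes it was 10.9-fold lower (8.28 to 14.8) in med16-2 at high phosphate and 11.8-fold lower (8.93 to 16.4) at low phosphate, in the direction the labels give. The 15 other Mediator subunits measured had no member meeting the size rule in any comparison, and their medians in med16-2 over Col-0 were 0.20, above 9815 of 10000 random lists, at high phosphate and 0.09, above 8055 of 10000 random lists, at low phosphate. The 8 reference genes, among them ACT7, UBQ10 and PP2AA3, also had 0 members meeting the rule, with medians of 0.01 and -0.01 for phosphate in Col-0 and med16-2 and of 0.07 and 0.12 for genotype at high and low phosphate.

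**Figure D1:**
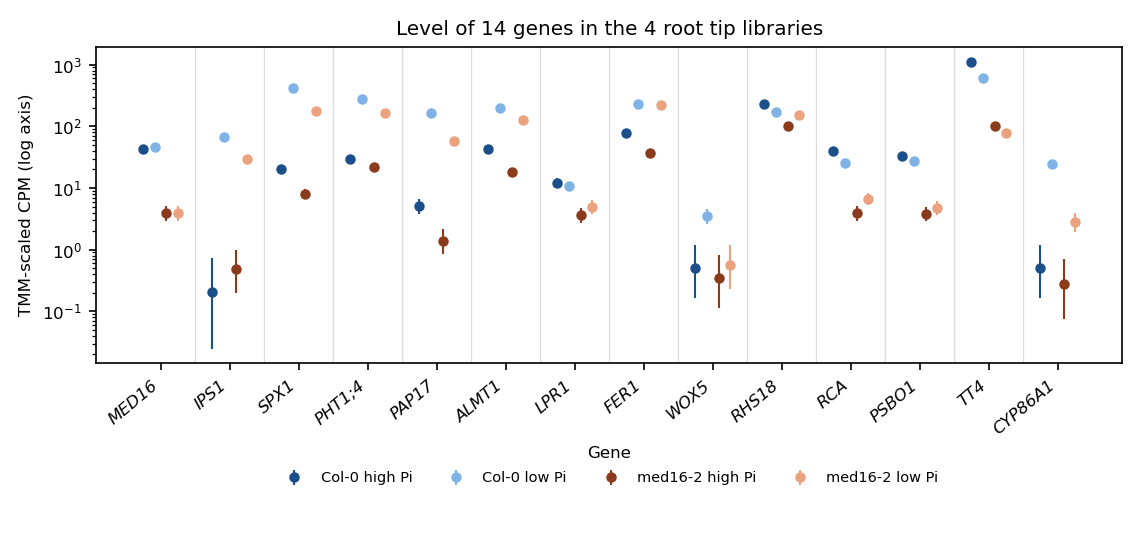
TMM-scaled CPM (log axis) of 14 genes in the 4 libraries, as points with exact Poisson 95% intervals that cover counting error only; several of the genes were picked after their values had been seen. MED16 lay lower in both med16-2 libraries, and IPS1, SPX1, PHT1;4 and PAP17 lay higher at low phosphate in both genotypes.

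The comparison of low with high phosphate in Col-0 asked which transcripts of the wild-type root tip differ with phosphate supply. Genes of the systemic phosphate starvation response were higher at low phosphate: 24 of the 26 measured members of that list met the size rule as higher and 0 as lower, with a list median of 2.48, above all 10000 random lists. The ferritin gene FER1 and 4 suberin genes were also higher, while the iron superoxide dismutase gene FSD1 and the iron transporter gene IRT1 were lower. In all, 606 genes were higher and 278 lower at low phosphate, of which 164 and 30 differed at least 4-fold. Cell cycle genes were close to equal, with 0 of 26 meeting the rule.

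Among phosphate starvation genes, the non-coding RNA gene IPS1 (AT3G09922) had 2 counts at high and 1077 at low phosphate, 266-fold higher (91.8 to 2748), and its relative AT4 (AT5G03545) was 30.0-fold higher (26.0 to 35.0). The SPX domain genes SPX1 (AT5G20150) and SPX3 (AT2G45130), which encode phosphate sensors, were 20.8-fold (18.1 to 24.1) and 31.9-fold (13.8 to 132) higher. Of the phosphate transporter genes, PHT1;4 (AT2G38940) was 9.46-fold higher (8.41 to 10.7), and PHT1;2 (AT5G43370) had 3 and 871 counts, 154-fold higher (61.1 to 871) a value left uncertain by near-identical neighbours that can share its reads. The purple acid phosphatase gene PAP17 (AT3G17790) was 31.7-fold higher (24.2 to 43.2). G3PP1 (AT3G47420) and the phosphatase gene PECP1 (AT1G17710) were 75.7-fold (52.9 to 117) and 63.5-fold (41.6 to 108) higher. PAP10 and PAP24, with log2 ratios of 0.40 and 0.87, were the 2 measured members that did not meet the rule.

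In the list of the local phosphate response, in which the transcription factor STOP1 acts on the malate channel gene ALMT1 in root tips, 3 of 16 measured members were higher and the median was 0.25, above 9991 of 10000 random lists. With a mean CPM of at least 5 that median was 0.12. ALMT1 (AT1G08430) was 4.61-fold higher (4.17 to 5.13). STOP1 and the ferroxidase gene LPR1 had log2 ratios of -0.10 (-0.21 to 0.01) and -0.17 (-0.51 to 0.18). The iron storage list had 2 of 6 measured members higher, a median of 0.61, above 9985 of 10000 random lists, and included the ferritin gene FER1 (AT5G01600), 2.97-fold higher (2.75 to 3.22). The iron uptake list had a median of -0.34, below 9998 of 10000 random lists, with 2 of 15 members higher and 1 lower. IRT1 (AT4G19690) was 4.77-fold lower (2.76 to 8.98), the nicotianamine synthase genes NAS1 and NAS2 were higher at log2 ratios of 1.1 and 1.01, and FIT, the regulator of iron uptake, had a log2 ratio of -0.96 (-1.24 to -0.69).

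Among cell type and growth lists, the differentiated endodermis list had 4 of 11 measured members higher and a median of 0.28, above 9978 of 10000 random lists. The 4 were the suberin genes CYP86A1, FAR4, GPAT5 and ASFT, at log2 ratios of 5.48, 3.90, 2.76 and 1.01, while CASP1 of the Casparian strip was at 0.15. The stem cell niche list had 2 of 16 members higher and a median of 0.23, above 9954 of 10000 random lists. Those were WOX5, the quiescent centre transcription factor, at 5 and 56 counts and 6.34-fold higher (2.79 to 22.1), and BRAVO at a log2 ratio of 1.08, while PLT1 had a log2 ratio of -0.35 (-0.59 to -0.10). None of the 19 root hair genes met the rule, although 17 had log2 ratios below 0 and the median was -0.43, below all 10000 random lists. The root cap, xylem and cell cycle lists had 0 members meeting the rule and medians of 0.00, 0.07 and -0.02. The root cap and cell cycle medians took the opposite sign when libraries were scaled by total counts. In the phloem list 1 of 5 members, NEN4, was higher, and the median was 0.32, above 9601 of 10000 random lists. Of 4 lateral root initiation genes measured, PUCHI was higher at a log2 ratio of 1.48, and LBD16, GATA23 and LBD18 were at 0.93, 0.72 and -0.34.

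The heat shock and touch list had 4 of 7 measured members higher and a median of 1.04, above all 10000 random lists, with HSP90.1 and HSP70-4 at log2 ratios of 2.06 and 1.77 and the touch gene TCH3 at 1.04. In the auxin list GH3.3 and IAA5, early auxin-responsive genes, were the 2 of 15 that were higher, and the median was 0.15, above 9947 of 10000 random lists. The defence list had a median of 0.14, above 9200 of 10000 random lists, with VSP1 and CHI-B higher at 2.29 and 1.97 and WRKY70 lower at -1.08. The cold list had 0 of 8 members meeting the rule and a median of -0.23, below 9404 of 10000 random lists, and the photosynthetic list 1 of 6 lower, RBCS1A, with a median of -0.49, below 9919 of 10000 random lists. Outside the lists, AT2G04460, a pseudogene in the TAIR10.1 annotation, had 0 counts at high and 1940 at low phosphate, at least 399-fold higher against a floor of 3 counts. AT2G18150 had 0 and 327 counts, at least 67.3-fold higher. FSD1 (AT4G25100) was 16.2-fold lower (13.6 to 19.6) at low phosphate, the glucosyltransferase gene UGT84A1 10.98-fold lower (7.94 to 15.9), and the early light-induced protein genes ELIP2 and ELIP1 7.37-fold (5.74 to 9.69) and 4.81-fold (4.08 to 5.71) lower. AT2G23910 and the pseudogene AT4G06477 were 5.09-fold (4.45 to 5.85) and 5.02-fold (3.04 to 8.91) lower.

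The same comparison in med16-2 asked which phosphate differences are present without full MED16 function. Most phosphate starvation genes were again higher at low phosphate, 20 of 26 measured members with 0 lower, and the list median was 1.84, above all 10000 random lists. Iron storage genes were higher in 5 of 6 cases, with a median of 1.58, above all 10000 random lists, and FSD1 had the largest ratio among lower genes with a mean CPM of at least 5. In all, 422 genes were higher and 193 lower, of which 144 and 31 differed at least 4-fold. Among the 422 were 57 ribosomal RNA, mitochondrial and plastid loci, in a library where the 18S locus took 1.37% of counts against 0.10% at high phosphate, and without such loci 365 genes were higher and 193 lower.

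IPS1 had 7 counts at high and 366 at low phosphate, 57.4-fold higher (29.5 to 154), and AT4 was 121-fold higher (79.3 to 207). SPX1 was 22.1-fold higher (18.3 to 27.0), PAP17 41.1-fold higher (27.0 to 69.3), PHT1;4 7.6-fold higher (6.76 to 8.60) and G3PP1 104-fold higher (63.7 to 197). SPX3 had 1 and 52 counts, 41.1-fold higher (10.5 to 2457), PHT1;2 had 2 and 415 counts, 195-fold higher (67.0 to 2018) with the same uncertainty from its neighbours, and PECP1 was 47.0-fold higher (23.1 to 139.9). PLDZ2, MGD3 and SQD2, genes of membrane lipid remodelling that were higher in Col-0, had log2 ratios of 0.46, 0.79 and 0.52 and did not meet the rule in med16-2. PAP12 and PHF1, outside that group and also higher in Col-0, did not meet it either, at 0.75 and 0.95. The lipid remodelling genes SQD1, MGD2, NPC4 and GDPD1 did meet it, at 1.58, 1.38, 4.10 and 2.49. ALMT1 was 7.20-fold higher (6.31 to 8.26), STOP1 had a log2 ratio of -0.20 (-0.30 to -0.11) and LPR1 of 0.44 (-0.12 to 1.00), within a local phosphate list that had 3 of 16 members higher and a median of 0.23, above 9993 of 10000 random lists. With a mean CPM of at least 5 that median was 0.11.

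FER1 was 6.07-fold higher (5.53 to 6.68) at low phosphate in med16-2, and the ferritin gene FER4 and the vacuolar iron transporter-like gene VTL2 were 3.22-fold (2.60 to 4.04) and 4.38-fold (1.71 to 16.0) higher. The iron uptake list had 3 of 15 members lower, 0 higher and a median of -0.23, below 9993 of 10000 random lists. IRT1 had 79 and 2 counts, 27.1-fold lower (9.01 to 283), and the iron deficiency regulator gene BHLH39 had 52 and 2 counts, 17.9-fold lower (5.83 to 188). The transporter gene OPT3 was 5.40-fold lower (3.84 to 8.0), while FIT had a log2 ratio of -0.55 (-0.76 to -0.34). All 19 root hair genes had log2 ratios above 0 and none met the rule, with a median of 0.47, above all 10000 random lists. The endodermis list had 2 of 11 members higher, CYP86A1 at a log2 ratio of 3.17 and FAR4 at 1.92. Its median was 0.04, above 8056 of 10000 random lists, and turned to below 0 with a mean CPM of at least 5.

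WOX5 had 5 and 7 counts in med16-2, a log2 ratio of 0.68 (-1.16 to 2.72), and PLT1 a log2 ratio of 0.26 (0.02 to 0.50). The stem cell niche, cell cycle, root cap, xylem and phloem lists had 0 members meeting the rule. The cell cycle median was -0.17, below all 10000 random lists, and the root cap median -0.22, below 9990 of 10000 random lists. The xylem median was 0.23, above 9955 of 10000 random lists, the phloem median 0.48, above 9943 of 10000 random lists, and the stem cell niche median 0.02. Heat shock genes HSP90.1, HSP70-4 and HSFA2 were higher, at log2 ratios of 1.87, 1.80 and 1.2, in a list with a median of 0.59, above all 10000 random lists. The auxin and defence lists had 0 members meeting the rule and medians of -0.08, below 9062 of 10000 random lists, and of 0.22, above 9889 of 10000 random lists. In the cold list the transcription factor gene CBF1 had 2 and 11 counts, 5.40-fold higher (1.41 to 59.9), and the median was 0.23, above 9660 of 10000 random lists. The cold median was 0.0261 with a mean CPM of at least 5. The photosynthetic list had 0 of 6 members meeting the rule and a median of 0.70, or 0.43 with RBCS1A, at 0 counts at high phosphate, set to its bound. None of the 4 lateral root genes met the rule. Outside the lists, AT2G04460 had 0 and 587 counts, at least 229.7-fold higher. FSD1 was 30.4-fold lower (15.6 to 81.6), AGP30 was 5.43-fold lower (4.5 to 6.63) and AT4G37710 was 5.62-fold lower (3.16 to 11.7). AT5G57785 had 12 and 1 counts, 7.10-fold lower (1.51 to 437), and AT4G39675 had 28 and 3 counts, 6.94-fold lower (2.46 to 40.9).

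**Figure D2:**
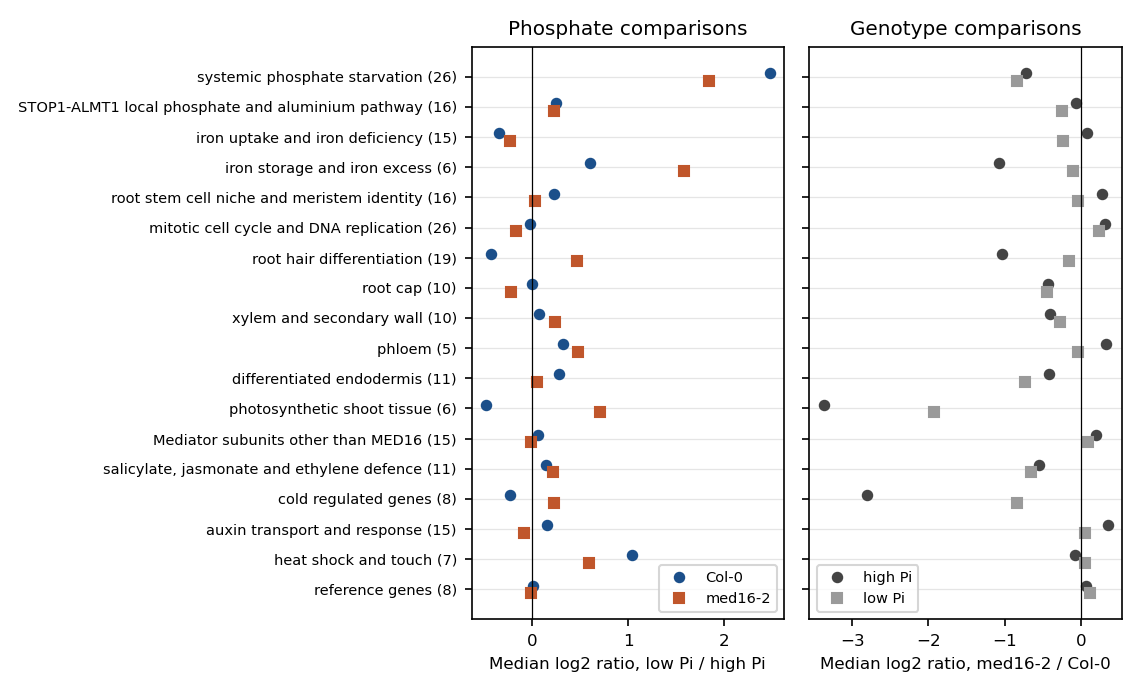
Median log2 ratio of the 18 gene lists with at least 5 measured members, low over high phosphate by genotype on the left and med16-2 over Col-0 by phosphate level on the right; the number of members is in parentheses. The systemic phosphate starvation list lay farthest to the right for phosphate in both genotypes (2.48 and 1.84), and the photosynthetic list farthest to the left for genotype at both phosphate levels (-3.38 and -1.92).

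The comparison of med16-2 with Col-0 at high phosphate asked which transcripts differ with MED16 when phosphate is ample. Most of the differences were towards lower counts in the mutant, with 1186 genes lower and 133 higher, of which 278 and 14 differed at least 4-fold. With a pseudocount of 5 in place of 0.5 these were 1141 lower and 64 higher. Lower in med16-2 were 7 of 8 cold regulated genes, 11 of 19 root hair genes, 6 of 6 photosynthetic genes and 8 of 26 phosphate starvation genes. Cell cycle genes had 0 of 26 members meeting the rule and a median of 0.32, above all 10000 random lists. Of the 1186 genes that were lower, 35 were ribosomal RNA or organelle loci, and mitochondrial loci took 0.23% of counts in med16-2 against 0.50% in Col-0.

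In the cold list 7 of 8 measured members were lower in med16-2 and the median was -2.80, below all 10000 random lists. That median was -1.69 with a mean CPM of at least 5, -1.96 without the member of largest ratio and -3.65 with no filter. RD29A (AT5G52310) had 152 counts in Col-0 and 3 in med16-2, 63.7-fold lower (24.9 to 363), and the transcription factor gene CBF1 had 21 and 2, 12.6-fold lower (3.75 to 135). KIN2 was 30.6-fold lower (21.3 to 47.3), and its close copy KIN1 had 24 and 1 counts, 23.9-fold lower (5.72 to 1442), and the 2 can share reads. COR47 was lower at a log2 ratio of -1.08, and ERD10, at -0.90, was the member that did not meet the rule. All 6 measured photosynthetic genes were lower, with a median of -3.38, below all 10000 random lists. The Rubisco activase gene RCA was lower at a log2 ratio of -3.35, RBCS1A had 108 counts in Col-0 and 0 in med16-2, at least 52.6-fold lower, and the light-harvesting gene LHB1B2 (AT2G34420) was 40.5-fold lower (28.1 to 62.9), where members of the LHCB1 and RBCS families can share reads.

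Of 19 root hair genes 11 were lower in med16-2 and 0 higher, with a median of -1.03, below all 10000 random lists. The log2 ratio was -1.32 for RHS12, -1.23 for RHS18 and -1.02 for RSL4, the transcription factor gene of root hair growth. In the phosphate starvation list 8 of 26 members were lower and 0 higher, with a median of -0.72, below all 10000 random lists. That median was -0.42 with a mean CPM of at least 5. AT4 was 13.9-fold lower (8.86 to 24.2), SPX1 2.53-fold lower (2.01 to 3.22) and PAP17 3.6-fold lower (2.14 to 6.48). PHT1;4 had a log2 ratio of -0.42 (-0.66 to -0.19), and IPS1 and SPX3 had under 10 counts in both libraries and did not meet the rule. ALMT1 was 2.39-fold lower (2.04 to 2.81) and LPR1 3.35-fold lower (2.42 to 4.76), in a local phosphate list with 4 of 16 members lower and a median of -0.07, below 8048 of 10000 random lists. STOP1 itself had a log2 ratio of 0.26 (0.16 to 0.36). The iron storage list had 4 of 6 members lower and a median of -1.08, below 9995 of 10000 random lists, with FER1 2.1-fold lower (1.88 to 2.36) and FER4 at a log2 ratio of -1.34. In the iron uptake list OPT3 alone met the rule, as higher at a log2 ratio of 1.03, the median was 0.08, above 7415 of 10000 random lists, and FIT and IRT1 had log2 ratios of 0.51 (0.29 to 0.74) and 0.08 (-0.44 to 0.62).

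The auxin list had 2 of 15 members higher, GH3.3 and IAA5, and a median of 0.35, above all 10000 random lists. GH3.3 had 3 counts in Col-0 and 36 in med16-2, 7.14-fold higher (2.59 to 41.7). The stem cell niche, phloem, root cap, xylem and heat shock lists had 0 members meeting the rule. The stem cell niche and phloem medians were 0.27, above 9983 of 10000 random lists, and 0.32, above 9747 of 10000 random lists. Without its member of largest ratio the phloem median was 0.0315. The root cap and xylem medians were -0.43, below 9976 of 10000 random lists, and -0.41, below 9921 of 10000 random lists, and the heat shock median was -0.08. In the endodermis list 1 of 11 members was lower, CASP5 at a log2 ratio of -1.23, and the median was -0.42, below 9938 of 10000 random lists. In the defence list 1 of 11, PR4, was lower at -1.64, and the median was -0.55, below 9969 of 10000 random lists. Among 4 lateral root genes LBD18 was lower at -1.02. The ratios of CYCB1;1, PLT1 and WOX5 were 0.32 (0.06 to 0.59), -0.30 (-0.55 to -0.05) and -0.55 (-2.67 to 1.57) on the log2 scale. Outside the lists, GRP9 had 71 counts in Col-0 and 0 in med16-2, at least 34.6-fold lower. UGT84A1 was 61.7-fold lower (30.3 to 183), the cell wall gene XTH31 35.2-fold lower (26.8 to 48.1), and AT5G37990 had 92 and 2 counts, 54.1-fold lower (18.1 to 563). The pseudogene AT5G35935 was 19.5-fold higher (12.9 to 32.4) in med16-2, and among genes with a mean CPM of at least 5 the next largest ratios upwards were those of AT5G26270, AT4G37850, AT5G51500, AT3G23570 and the nitrilase gene NIT2, from 3.81-fold down to 2.60-fold (2.31 to 2.94) higher.

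At low phosphate the comparison of med16-2 with Col-0 asked the same of roots short of phosphate. Again most differences were towards lower counts in the mutant, with 1147 genes lower and 195 higher, of which 363 and 38 differed at least 4-fold. Phosphate starvation genes were lower in the mutant in 12 of 26 cases and higher in 0, with a median of -0.84, below all 10000 random lists. Also lower were 4 of 11 endodermis genes, 6 of 6 photosynthetic genes and 3 of 8 cold regulated genes, while 0 of 19 root hair genes met the rule. Of the 195 genes that were higher, 19 were ribosomal RNA or organelle loci, among them the 18S locus AT3G41768, 14.5-fold higher (14.3 to 14.8), which took 1.37% of counts in med16-2 against 0.10% in Col-0.

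RNS1, a ribonuclease gene of phosphate starvation, was 8.86-fold lower (7.09 to 11.3) in med16-2, PECP1 5.92-fold lower (5.20 to 6.77) and NPC4 4.11-fold lower (3.25 to 5.31). AT4 was 3.45-fold lower (3.28 to 3.62), SPX3 3.40-fold lower (2.53 to 4.72), PAP17 2.78-fold lower (2.56 to 3.02), SPX1 2.39-fold lower (2.27 to 2.51) and IPS1 2.26-fold lower (2.01 to 2.55). PHT1;4 had a log2 ratio of -0.74 (-0.82 to -0.66). LPR1 was 2.20-fold lower (1.64 to 3.02) and the polygalacturonase inhibitor gene PGIP2 5.33-fold lower (3.28 to 9.70), the 2 of 16 local phosphate genes that were lower. ALMT1 had a log2 ratio of -0.62 (-0.71 to -0.53), STOP1 of 0.16 (0.06 to 0.25), and the list median was -0.25, below 9894 of 10000 random lists. In the iron uptake list 3 of 15 members were lower and the median was -0.24, below 9753 of 10000 random lists, a position inside the central 95% of random lists under every alternative run except DESeq2 size factors. IRT1 had 17 counts in Col-0 and 2 in med16-2, 5.38-fold lower (1.55 to 58.3), BHLH39 had 31 and 2, 9.68-fold lower (3.03 to 103), and NAS2 was 3.84-fold lower (2.55 to 6.19). FIT had a log2 ratio of 0.93 (0.67 to 1.19) and FER1 of -0.04 (-0.11 to 0.03), the latter turning to above 0 with upper-quartile scaling. The iron storage list had 1 of 6 members lower, VTL2, and a median of -0.10, below 7375 of 10000 random lists.

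In the endodermis list 4 of 11 members were lower, CYP86A1 at a log2 ratio of -3.14, FAR4 at -2.82, GPAT5 at -2.46 and CASP5 at -1.57, and the median was -0.74, below all 10000 random lists. The root cap list had 3 of 10 members lower, RCPG, CEL3 and BFN1, and a median of -0.44, below 9989 of 10000 random lists. WOX5 had 56 counts in Col-0 and 7 in med16-2, 5.79-fold lower (2.79 to 16.0), and was the 1 of 16 stem cell niche genes that met the rule. The list median was -0.05, and PLT1 had a log2 ratio of 0.30 (0.06 to 0.53). PUCHI was the lateral root gene that was lower, at -2.43. The cell cycle list had 0 of 26 members meeting the rule and a median of 0.23, above 9997 of 10000 random lists, with CYCB1;1 at 0.26 (0.00 to 0.53). The root hair, xylem, phloem, auxin and heat shock lists had 0 members meeting the rule. The root hair median was -0.15, below 9933 of 10000 random lists, and the xylem median -0.27, below 9745 of 10000 random lists. The phloem, auxin and heat shock medians were -0.05, 0.05 and 0.05, and the last turned to below 0 with no filter or with a mean CPM of at least 5.

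The defence list had 5 of 11 members lower and a median of -0.66, below 9997 of 10000 random lists (-1.34 with no filter), with the transcription factor gene ERF1 at a log2 ratio of -2.60, PR4 at -2.04, VSP1 at -1.67 and the jasmonate repressor gene JAZ10 at -1.65. In the cold list 3 of 8 members were lower and the median was -0.84, below 9995 of 10000 random lists. RD29A had 306 and 3 counts, 67.3-fold lower (26.6 to 382), KIN2 was 34.8-fold lower (22.2 to 61.8), and KIN1 had 73 and 1 counts, 37.6-fold lower (9.76 to 2245), with the same uncertainty as above. All 6 photosynthetic genes were lower, with a median of -1.92, below 9999 of 10000 random lists and RCA at -1.94. Outside the lists, GRP9 had 364 counts in Col-0 and 0 in med16-2, at least 93.2-fold lower. AT5G37990 was 93.8-fold lower (50.4 to 231) and the transporter gene UMAMIT20 48.7-fold lower (21.1 to 202), and AT5G57785 had 221 and 1 counts, 113-fold lower (30.2 to 6737). Among genes with a mean CPM of at least 5, those with the largest ratios upwards were the pseudogenes AT4G06477 and AT5G35935, 18.0-fold (11.7 to 30.6) and 12.01-fold (8.85 to 17.0) higher, the non-coding locus AT1G15405, 13.5-fold (8.82 to 22.8) higher, the 18S locus given above, the locus AT2G01021, 13.0-fold (12.6 to 13.3) higher, and the mitochondrial locus ATMG01080, 10.9-fold (7.53 to 16.9) higher.

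Each comparison was then set against its counterpart, with which it shares no library. In the same direction in both genotypes, 201 genes were higher and 44 lower at low phosphate, where independent lists of these sizes would share 13.7 and 2.87 (n1 × n2 / N with N = 18692), and 40 genes met the rule in opposite directions. Both phosphate comparisons had SPX1, SPX3, IPS1, AT4, PAP17, PHT1;4, G3PP1, PECP1, ALMT1 and FER1 among the higher genes and FSD1 and IRT1 among the lower. Between genotypes, 588 genes were lower and 27 higher in med16-2 at both phosphate levels, where independent lists would share 72.8 and 1.39 and a pseudocount of 5 gave 521 and 13, and 27 genes met the rule in opposite directions. The figure for independent lists takes every gene as equally likely to be called, and was not computed for opposite directions. It is therefore no full measure of chance overlap. MED16, LPR1, AT4, SPX1, PAP17, RNS1, NPC4, RD29A, KIN2 and RCA were lower in med16-2 at both levels. Across genes, which are not independent replicates, Pearson's r between log2 ratios was 0.45 for the phosphate pair and 0.61 for the genotype pair. The 606 genes higher at low phosphate in Col-0 had a median log2 ratio of 1.49 there and 0.68 in med16-2, and the 422 chosen in med16-2 had 1.61 there and 0.92 in Col-0, so each set had the larger median in the libraries it was chosen on. In an additive edgeR quasi-likelihood model with 1 residual degree of freedom, 146 genes were higher and 35 lower with low phosphate and 148 higher and 1218 lower in med16-2 at a Benjamini-Hochberg adjusted p under 0.05. Of these, 104 and 15 were among the genes meeting the size rule in both genotypes, and 12 and 483 among those meeting it at both phosphate levels. The same model in DESeq2 (Wald test, Benjamini-Hochberg adjusted p under 0.05) gave 171 higher and 57 lower with low phosphate and 37 higher and 796 lower in med16-2. Of these, 109 and 18, and 5 and 384, were among the genes meeting the size rule in both pairs. Both models use the same 4 libraries, and their residual is the interaction of genotype and phosphate. Genes with similar ratios in both pairs have a small residual, so these overlaps are no separate check. The adjusted p-values do not measure variation between plants.

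**Figure D3:**
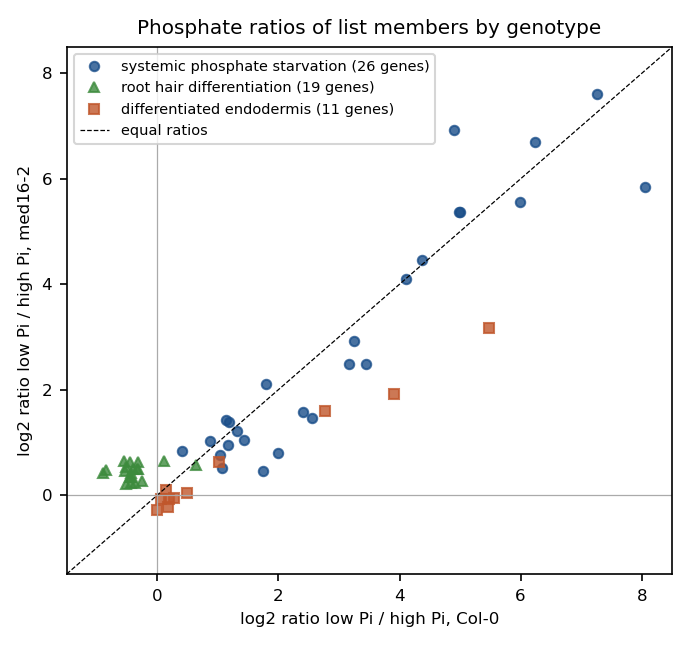
Log2 ratio of low over high phosphate in Col-0 (horizontal axis) and med16-2 (vertical axis), 1 point per gene of the systemic phosphate starvation, root hair and endodermis lists, with a dashed line where both are equal. All 26 phosphate starvation genes lay above 0 on both axes, and 18 of 19 root hair genes lay above the dashed line.

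The difference between the phosphate log2 ratios of med16-2 and Col-0 asked for which genes the phosphate difference depends on the genotype. It was at least 2-fold with an interval excluding 0 for 833 genes, 429 with the larger ratio in med16-2 and 404 with the larger ratio in Col-0. With no residual degree of freedom this difference has no test. Of the root hair genes 5 of 19 and of the iron storage genes 2 of 6 had the larger ratio in med16-2, and the suberin genes CYP86A1 and FAR4 and the glutathione transferase gene GSTF6 had the larger ratio in Col-0. Of the 429, 35 were ribosomal RNA or organelle loci, and scaling by total counts gave 357 and 500 genes in place of 429 and 404, and a pseudocount of 5 gave 388 and 246.

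Of 19 root hair genes 5 met the rule, with the larger ratio in med16-2 each time, 18 were positive and the median was 0.83, above all 10000 random lists. RHS15, RSL4 and PRP1 had differences of 1.32, 1.31 and 1.2 on the log2 scale. The iron storage list had FER1 at 1.03 (0.85 to 1.21) and FER4 at 1.22, 2 of 6 members, and a median of 0.96, above 9999 of 10000 random lists. In the phosphate starvation list AT4 was at 2.01 (1.34 to 2.69), while RNS1, MGD3, PLDZ2 and IPS1 were at -1.1, -1.2, -1.29 and -2.21 (-4.29 to -0.14), and the median was -0.15, below 9989 of 10000 random lists. SPX1, SPX3, PAP17 and PHT1;4 were at 0.09 (-0.25 to 0.43), 0.37 (-2.34 to 3.07), 0.37 (-0.38 to 1.12) and -0.32 (-0.56 to -0.07) and did not meet the rule, and that of SPX3 took the opposite sign with a pseudocount of 5. ALMT1, LPR1 and STOP1 were at 0.64 (0.40 to 0.88), 0.61 (-0.02 to 1.24) and -0.10 (-0.24 to 0.04). PGIP2 was the 1 local phosphate gene meeting the rule, at -1.38, and the list median of 0.06 took the opposite sign with scaling by total counts.

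In the iron uptake list BHLH39, IRT1, OPT3 and NAS2 met the rule, at -3.56, -2.51 (-4.48 to -0.53), -1.93 and -1.43, FIT was at 0.41 (0.07 to 0.75), and the median was -0.02, below 6808 of 10000 random lists. The endodermis list had all 11 members below 0 and a median of -0.39, below 9997 of 10000 random lists, with CYP86A1 and FAR4 at -2.31 and -1.99. WOX5 was at -1.99 (-4.01 to 0.04) and PLT1 at 0.60 (0.26 to 0.94) in a stem cell niche list with 0 of 16 members meeting the rule and a median of -0.34, below 9999 of 10000 random lists. In the auxin list GH3.3 and IAA5 were at -3.70 and -1.67 and the median was -0.24, below 9994 of 10000 random lists. The defence list had ERF1, CHI-B and JAZ10 at -2.27, -1.37 and -1.1 and WRKY70 at 1.31, with a median of -0.06, below 7434 of 10000 random lists, and the cold list CBF1 and GOLS3 at 3.35 and 1.19, with a median of 0.15, above 8224 of 10000 random lists. The photosynthetic list had RCA at 1.41 as its 1 member of 6 meeting the rule. The cell cycle, root cap, xylem, phloem, heat shock and Mediator lists had 0 members meeting the rule and medians of -0.15, -0.33, 0.13, -0.05, -0.19 and -0.13. The medians of the iron uptake, phloem, defence and cold lists took the opposite sign with a mean CPM of at least 5 or without their member of largest ratio.

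Outside the lists, the glutathione transferase gene GSTF6 (AT1G02930) had 33 and 1510 counts at high and low phosphate in Col-0 and 80 and 82 in med16-2. Its close copy GSTF7 had 32, 469, 98 and 50 in the same order. The differences were -4.53 and -3.89 for these genes, which can share reads. The peroxidase gene AT5G39580 had 114, 940, 306 and 108 counts, the transcription factor gene WRKY48 25, 325, 71 and 53, AT2G43620 19, 931, 20 and 58, and AT5G22580 15, 253, 37 and 37. The differences were -3.61, -3.17, -3.14 and -3.10. Among genes with a mean CPM of at least 5, the largest differences towards med16-2 were those of AT1G15405 at 5.53, the pseudogene AT4G06477 at 5.37, the mitochondrial loci ATMG01080 and ATMG00160 at 4.85 and 3.65, the 18S locus AT3G41768 at 4.73 and AT2G01021 at 4.28, in the direction of the 1.37% share of the 18S locus in med16-2 at low phosphate. FER1, PAP17, LPR1, FRO3, FER4, UGT84A1, PLDZ2, RCA, GAPA, LHB1B2, CASP5, ASFT, FAR4, CHI-B and TCH3 are among the named genes that overlap another annotated locus in TAIR10.1. With libraries that do not keep strand, their counts can lack reads that were set aside as ambiguous. Depending on the counting settings, which are not given, they can also include reads of the other locus.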

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

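All tests weighed here were chosen after the results they bear on had been seen. Whether a phosphate ratio differs between genotypes, or a genotype ratio between phosphate levels, was not tested, since a model with that interaction leaves no residual degree of freedom.

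Root hair genes stood out because the phosphate ratio had opposite signs in the genotypes, with a list median of -0.43 in Col-0 and 0.47 in med16-2. A longer root tip sample would raise genes expressed away from the tip and lower those of the tip. The median difference of phosphate ratios was -0.39 in the endodermis list, with 0 of 11 members above 0 (-0.27 in the 7 members outside suberin synthesis), against 0.83 in the root hair list, which goes against tip length. The stem cell niche, root cap and cell cycle medians of -0.34, -0.33 and -0.15 go with it, and that of the xylem list, 0.13, was above 8818 of 10000 random lists, so tip length and a genotype effect cannot be told apart from lists that point both ways. Tip length could also bear on the genotype ratios at high phosphate. There the root hair, endodermis and xylem medians were -1.03, -0.42 and -0.41, and the cell cycle and stem cell niche medians 0.32 and 0.27. The root cap and phloem medians, -0.43 and 0.32, go the other way, and this was not tested. Scaling moved the median of all genes by at most 0.0748 (log2), less than the root hair difference, which argues against scaling, while an effect of single samples stays open and was not tested.

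Reads aligned to several places (36.6%) and reads in no annotated gene (4.43%) stood out in the med16-2 low phosphate library because these lines lie outside the gene counts and were above their shares in the other 3 libraries. In this library the 18S locus was also high, at a log2 ratio of 3.86 against Col-0 at low phosphate. The test set for a larger amount of RNA without a poly(A) tail asked for medians of plastid and mitochondrial loci above 0 beyond the spread of random lists. This had to hold both for the difference of phosphate ratios and against Col-0 at low phosphate. The medians of the difference were 1.07 in plastid loci and 1.98 in mitochondrial loci (without ribosomal RNA loci and ATMG00030), the direction this explanation needs. Against Col-0 at low phosphate, however, plastid loci had a median of -0.24, which did not meet the test, beside 0.91 in mitochondrial loci. Of the mitochondrial ribosomal RNA loci, ATMG00020 took 0.556% of gene counts against 0.860% and ATMG01390 0.393% against 0.275%. At high phosphate the same medians were -1.37 in plastid and -1.28 in mitochondrial loci, so both were already lower in med16-2 there. The plastid median of -0.24 therefore does not by itself go against this explanation. With 1 library per group, RNA without a poly(A) tail and a difference in these loci themselves cannot be told apart. Whether RNA quality affected other genes of this library stays open.

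The photosynthetic list also had phosphate ratios of opposite sign, with medians of -0.49 in Col-0 and 0.70 in med16-2 (0.43 with RBCS1A at its bound). Opposite calls were also singled out: 40 genes met the size rule in opposite directions for phosphate in the 2 genotypes, and 27 for genotype at the 2 phosphate levels.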

How the results depend on the processing

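Of the alternatives, those set before the data were examined are given first. No paired analysis was possible because each group has 1 library and the groups share 1 replicate number, and no replicate could be left out for the same reason. No list median lying outside the central 95% of its random lists, and no value of the 16 fixed named genes that met the size rule, took the opposite sign under the alternatives run for it; the medians that did lay inside it. Other genes were not followed one by one. Counts are given here for phosphate in Col-0 (884 genes before), phosphate in med16-2 (615), genotype at high phosphate (1319), genotype at low phosphate (1342), the difference of phosphate ratios (833), the same phosphate direction in both genotypes (245) and the same genotype direction at both phosphate levels (615). They were 389, 252, 743, 636, 369, 126 and 347 with a mean CPM of at least 5, where fewer genes were compared, 2082, 1417, 2812, 2831, 1874, 582 and 1366 at 1.5-fold, 194, 175, 292, 401, 182, 68 and 161 at 4-fold, and 353, 216, 559, 638, 182, 97 and 254 with an interval beyond 2-fold, moves that follow from these rules. The edgeR additive model gave 1366 genes for genotype. With the other scalings, no filter, the pseudocount of 5, the DESeq2 model and, for phosphate, the edgeR model, all of these counts were within 1.5 times. By direction, the pseudocount of 5 moved 3 of them further: to 64 genes higher (133 before) for genotype at high phosphate, 246 with the larger ratio in Col-0 (404 before) for the difference, and 13 higher (27 before) for the same genotype direction. Leaving out ribosomal RNA and organelle loci, added after the data had been seen, gave 877, 558, 1284, 1321, 798, 240 and 613. List medians moved beyond the spread of random lists in 12 of 90 cases with no filter: 2.56 in the phosphate starvation list (2.48 before) for phosphate, Col-0; 2.11 in the phosphate starvation list (1.84 before), -0.42 in the iron uptake list (-0.23 before), 1.32 in the iron storage list (1.58 before), 0.40 in the photosynthetic list (0.70 before), 0.11 in the defence list (0.22 before) for phosphate, med16-2; -0.22 in the phosphate starvation list (-0.15 before), -0.20 in the iron uptake list (-0.02 before), 0.31 in the cold list (0.15 before) for the difference of phosphate ratios; -1.34 in the defence list (-0.66 before), -0.64 in the heat and touch list (0.05 before) for genotype, low phosphate; -3.65 in the cold list (-2.80 before) for genotype, high phosphate. With a mean CPM of at least 5 this held for 14 of 80: 2.56 in the phosphate starvation list (2.48 before), 0.12 in the local phosphate list (0.25 before), 0.90 in the heat and touch list (1.04 before) for phosphate, Col-0; 2.11 in the phosphate starvation list (1.84 before), 0.11 in the local phosphate list (0.23 before), -0.0645 in the endodermis list (0.04 before), 0.0261 in the cold list (0.23 before) for phosphate, med16-2; -0.42 in the phosphate starvation list (-0.72 before), -0.58 in the xylem list (-0.41 before), -1.69 in the cold list (-2.80 before) for genotype, high phosphate; -0.28 in the phosphate starvation list (-0.15 before), 0.30 in the xylem list (0.13 before) for the difference of phosphate ratios; -0.59 in the root cap list (-0.44 before), -0.26 in the heat and touch list (0.05 before) for genotype, low phosphate; the phloem and photosynthetic lists then had under 5 members and gave no value. With total counts it held for 6 of 90: -0.23 in the phosphate starvation list (-0.15 before), -0.22 in the cell cycle list (-0.15 before), 0.76 in the root hair list (0.83 before), -0.31 in the auxin list (-0.24 before), -0.10 in the reference genes list (-0.02 before) for the difference of phosphate ratios; 0.0333 in the cell cycle list (-0.02 before) for phosphate, Col-0. Without the member of largest ratio it held for 8 of 90: 2.41 in the phosphate starvation list (2.48 before), 0.90 in the heat and touch list (1.04 before) for phosphate, Col-0; 1.58 in the phosphate starvation list (1.84 before) for phosphate, med16-2; -0.0891 in the phosphate starvation list (-0.15 before), -0.0068 in the cold list (0.15 before) for the difference of phosphate ratios; -0.29 in the root cap list (-0.44 before) for genotype, low phosphate; 0.0315 in the phloem list (0.32 before), -1.96 in the cold list (-2.80 before) for genotype, high phosphate. Beyond the make-up of the lists, the cause was not tested. Medians outside the central 95% of random lists moved inside it for iron uptake (genotype, low phosphate), Mediator (genotype, high phosphate), the photosynthetic list (phosphate, both genotypes), defence (phosphate, med16-2), root hair (genotype, low phosphate) and auxin (phosphate, Col-0), the last 2 with unmatched lists alone. DESeq2 size factors, upper-quartile factors and unmatched random lists moved 0 of 90 medians, and all 80 values of the fixed named genes stayed within their counting intervals under 3 scalings and the pseudocount of 5, with MED16, FER1 and SPX3 crossing 0 in 1 comparison each. Depth limits genes at few counts most: IPS1, with 2 counts at high phosphate in Col-0, had an interval from 91.8-fold to 2748-fold.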

Other observations

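The lists described here, flavonol, chlorophyll and suberin synthesis, photosystem genes and leaf carbon assimilation, and all tests in this part were chosen after the values had been seen. Flavonol biosynthesis genes were lower in med16-2, 9 of 9 measured members at high phosphate and 8 of 9 at low phosphate, with medians of -3.39, below all 10000 random lists, and -2.24, below all 10000 random lists. The chalcone synthase gene TT4 had log2 ratios of -3.47 and -2.98, the flavonol synthase gene FLS1 of -3.49 and -3.51, and the transcription factor gene MYB12 of -2.97 and -1.60. Photosynthetic genes were lower in the same comparisons, and whether shoot tissue in the Col-0 samples added to the flavonol counts was not tested. In Col-0, 7 of 9 flavonol genes were lower at low phosphate, with a median of -1.46, below all 10000 random lists, and in med16-2 2 of 9, with a median of -0.39, below all 10000 random lists; for the difference the median was 0.68, above all 10000 random lists. Suberin synthesis and export genes were higher at low phosphate, 9 of 12 in Col-0 (median 1.86, above all 10000 random lists) and 6 of 12 in med16-2 (median 1.41, above all 10000 random lists). They were lower in med16-2 in 4 of 12 cases at high and 7 of 12 at low phosphate, with medians of -0.65, below 9946 of 10000 random lists, and -1.73, below 9999 of 10000 random lists, and the median difference of phosphate ratios was -0.87, below all 10000 random lists. The transporter gene ABCG6 had phosphate log2 ratios of 4.64 in Col-0 and 2.29 in med16-2, and the fatty acid hydroxylase gene CYP86B1 of 2.89 and 1.78.

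Photosystem and light harvesting genes were lower in med16-2 for 20 of 20 measured members at both phosphate levels, with medians of -3.20, below all 10000 random lists, and -2.70, below all 10000 random lists. PSBO1 had log2 ratios of -3.10 and -2.52, and LHCB5 of -3.65 and -2.84. For phosphate the medians were -0.07 in Col-0 and 0.23 in med16-2, with a median difference of 0.53. Chlorophyll biosynthesis genes were lower in med16-2 in 4 of 11 cases at high and 5 of 11 at low phosphate, with medians of -0.87, below 9993 of 10000 random lists, and -0.62, below 9951 of 10000 random lists; CRD1 was at -3.01 and -2.92 and PORB at -3.80 and -3.14. For phosphate none of the 11 met the rule, with medians of -0.21 in Col-0 and -0.06 in med16-2, and the median difference was 0.25. Leaf carbon assimilation genes, of which 8 of 19 passed the filter, were lower in med16-2 in 1 case at high phosphate (SHM1) and 2 at low phosphate (SHM1 and GOX2), with medians over those 8 of -0.23 and -0.23 for genotype, -0.06 and -0.16 for phosphate in Col-0 and med16-2, and 0.07 for their difference; of the 11 under the filter, 6 were lower with both phosphate levels summed. Plastid loci had genotype medians of -1.37 and -0.24. Mitochondrial loci had genotype medians of -1.28 and 0.91, with the ribosomal RNA loci ATMG00020 and ATMG01390 left out, and also ATMG00030, the locus with the next highest count.

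For the lower photosystem genes in med16-2, the 18 measured members outside the near-identical LHCB1, LHCB2 and RBCS families had medians of -3.06 and -2.57 at high and low phosphate, and 18 of 18 were lower at both, which argues against reads shared between paralogs as the whole cause. Shoot tissue in the Col-0 samples would bring leaf carbon assimilation transcripts too, and of 23 such genes (the 19 above with RCA, RBCS1A, GAPA and GAPB) 11 were at least 2-fold lower in med16-2 with an interval excluding equality, counts of both phosphate levels summed. These were RCA (806 counts in Col-0 and 138 in med16-2), RBCS1A (173 and 1), SHM1 (1384 and 545), GAPA, GAPB, GAPA-2, PRK, FBA2, SBPASE, HCEF1 and HPR, whereas CA1 had 13 and 8 counts, GOX1 6 and 3, FBA1 2 and 4, AT1G32470 9 and 3, and CA2, the 1 that was higher, 3 and 12. Members with more counts also failed the rule: AT3G60750 (9997 and 11416), GS2 (5113 and 6618), AT1G11860 (4321 and 4069), GLDP1 (3653 and 2969), GGT1 (1120 and 751), AGT (108 and 167) and GOX2 (102 and 54). Here 11 of these 23 genes were lower and the others not, and this test does not tell shoot tissue from a genotype effect on these genes in the root. There was no leaf library to give the level that shoot tissue would bring. Both explanations stay open, as does an effect of single samples, which was not tested. The leaf list was picked and widened after counts had been seen, and this test replaced earlier ones on the level of the same genes in Col-0, which needed such a leaf library. It asked whether all or none of the genes were lower. RCA, RBCS1A, GAPA and GAPB were already known to be lower when added, so none could not come out.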
